A study of Mus musculus with 8 samples.

How the data were processed

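Gastrocnemius muscle of 8 male mice on a C57BL6 background was analysed, 4 wild type and 4 homozygous for a targeted Bcat2 allele, per the labels. Per the labels' protocols, dams and weaned mice chose freely between a chow and a purified diet free of branched-chain amino acids, and the muscle was taken under isoflurane and frozen between cooled metal blocks. Total RNA with an A260:A280 ratio above 1.9 and an RNA integrity number above 7 went into TruSeq RNA v2 libraries, and 8 libraries were pooled per lane and read for 50 cycles from one end, per the labels' protocols.

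Reads were aligned to mm10 with TopHat 2.0.9, and uniquely mapped reads gave FPKM with Cufflinks 2.0.2, per the labels' protocols. The submitters' processing notes name Cufflinks 2.2.1 and CASAVA 1.8.2 instead, so the Cufflinks version is uncertain. The gene annotation and any strand setting are not given in the sources used here. The deposited unit is FPKM, fragments per kilobase of exon scaled to the mapped fragments of the library, in 1 column per mouse, with the authors' mean FPKM of each genotype beside them, per the file headers. The deposited table also holds flags of 0 or 1 for 2 thresholds of the authors' own p-value, per the file headers, and the test behind them is not given in the sources used here. Per a note in the deposited table, the Myh4 value of WT2 carried a Cufflinks error flag and was left out of the authors' mean. The Thrsp value of WT1 is blank.

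The table has 39009 rows under 38741 distinct symbols. Wild-type columns WT1 to WT4 were matched to the labelled mice by number. Columns KO5 to KO8 name the knockout group but match no single labelled knockout, so the age and weight of a knockout were not tied to a column, and the numbers pair no mice. A comparison with the GENCODE annotation of the same build found 37537 of the rows' gene identifiers, and for 29195 of them the deposited start plus 1 was the annotated start. Positions are therefore given from 1, as the deposited start plus 1.

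FPKM do not carry read totals. For genes with FPKM above 0 and under 0.3 in both a library and WT2, the log2 ratio of its FPKM to that of WT2 was taken. The mode of these ratios over genes (kernel SD 0.05), with its sign reversed, gave the log2 depth of the library relative to WT2. These relative depths give no read count, so no counting interval is printed, and precision rests on the spread between mice.

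For symbols on several rows, the row with the highest mean FPKM was used. Genes with a mean FPKM of at least 1 over the 8 mice were tested, 11118 in all. The test was limma-trend on log2(FPKM + 1), 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, with genotype as the only term. Fold changes are on the log2(FPKM + 1) scale, knockout minus wild type, which understates the change of genes with low FPKM. For single genes, an exact permutation test over the 35 splits of the mice (70 with labels) was run. The smallest 2-sided p it can give is 0.0286. The 30 gene lists were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and on ranks. Camera compares a list with the other genes, so list medians are given relative to the median of all tested genes.

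The lists and the test design were set before the data were examined. Named genes were Bcat2, then the 12 largest rises and the 12 largest falls among genes past the threshold with groups that did not overlap, leaving out Riken, Gm-numbered, LOC and accession-like names. Where fewer than 20 passed, genes with the smallest unadjusted p filled the number up to 20 and are said not to have passed. From each list the called members, at most 4, or else the member with the smallest p, were named. Other genes were chosen after their values were seen, also where this is not repeated beside their names. One gene is not reported here.

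Alternatives were pseudocounts of 0.1 and 0.5, no filter and a mean FPKM of at least 5, median-ratio and quantile scaling, each mouse left out in turn, other eBayes and weight settings, and summed rows. Alternatives added after seeing the data left out WT1 and KO6, removed a loess trend on transcript length and GC percent in each mouse (span 0.5), set FPKM of exactly 0 to missing, set the Myh4 value of WT2 to missing, took Bcat2 out of its list, or used relative depth as a covariate. The fitting code was tested on simulated data with 11117 genes and 4 mice per group. At a log2 change of 1 it recovered 46% of the changed genes, and at a log2 change of 2 it recovered 79%, with 8 false among 133 calls. The simulation changed 100 genes at each size and drew noise independently for each gene. The muscle data have correlated genes and few calls, so these rates check the code and may overstate the recovery in muscle. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.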

Results

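Messenger RNA was sequenced from the gastrocnemius, a calf muscle made largely of fast fibres, of 4 wild-type mice and 4 mice lacking Bcat2. Bcat2 encodes BCATm, the mitochondrial aminotransferase that takes the first step in the breakdown of leucine, isoleucine and valine and is abundant in muscle. The wild-type mice were 9 to 10 weeks old and weighed 24 ± 1.41 g (SD, n = 4), and the knockouts were 10 to 11 weeks old and weighed 19.5 ± 4.2 g (SD, n = 4). The weight difference of -4.5 g gave an exact permutation p = 0.143 (2-sided). Weights ran from 15 to 24 g in knockouts and from 22 to 25 g in wild type, so 4 mice per group leave a difference in weight open. FPKM summed to between 691168 and 896190 per library. Relative to the wild-type library WT2, depth ran from 0.437 in WT4 to 1.23 in WT3, with a mean of 0.932 ± 0.344 in wild type and 0.815 ± 0.281 in knockouts (SD, n = 4 each). WT1 and KO6 carried fat transcripts far above the other 6 mice, with Adipoq, an adipocyte hormone, at 674 and 311 FPKM against 4.49 to 49.9 FPKM. KO6 alone also carried skin keratins, with Krt14 at 108 FPKM against at most 0.365 FPKM elsewhere. All 37 rows on the mitochondrial chromosome were listed at 0 in every mouse.

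**Figure D1:**
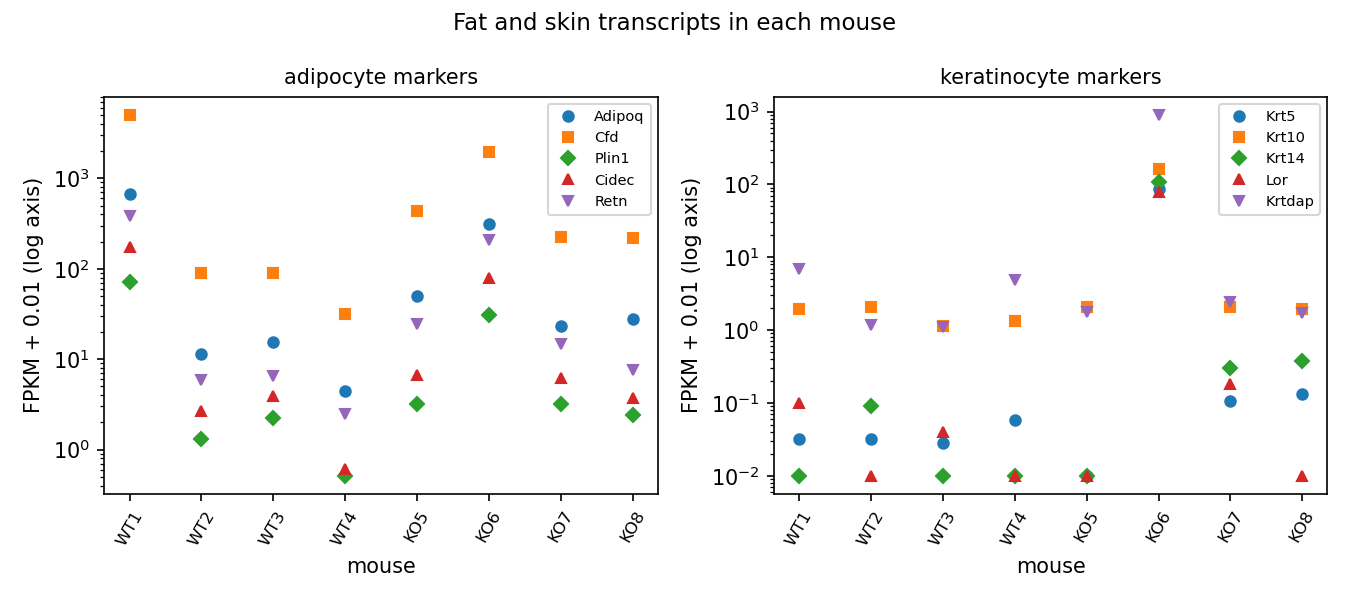
FPKM of 5 adipocyte markers (left) and 5 keratinocyte markers (right) in each mouse, on log axes after adding 0.01. WT1 and KO6 are highest for the adipocyte markers, with Adipoq at 674 and 311 FPKM, and KO6 alone is high for the keratinocyte markers, with Krt14 at 108 FPKM.

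The first question was whether the target transcript was lost in the mice labelled knockout. Bcat2 (ENSMUSG00000030826, mm10 chromosome 7, 45570153 to 45589710) stood at 53.2 ± 19.9 FPKM in wild type and 3.29 ± 1.37 FPKM in knockouts (SD, n = 4 each). The single wild-type libraries read 83.0, 42.7, 46.0 and 41.2 FPKM, and the knockouts read 2.89, 5.26, 2.91 and 2.09 FPKM. The knockout mean was thus 6.18% of the wild-type mean. Bcat2 fell by 3.65 on the log2 scale (SE 0.28, 95% interval -4.30 to -3.00, limma adjusted p = 0.00245), lower in 4 of 4 knockouts. The exact permutation p was 0.0286, the smallest that 4 against 4 mice allow. Which exons the allele lacks is not given by gene-level values.

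**Figure D2:**
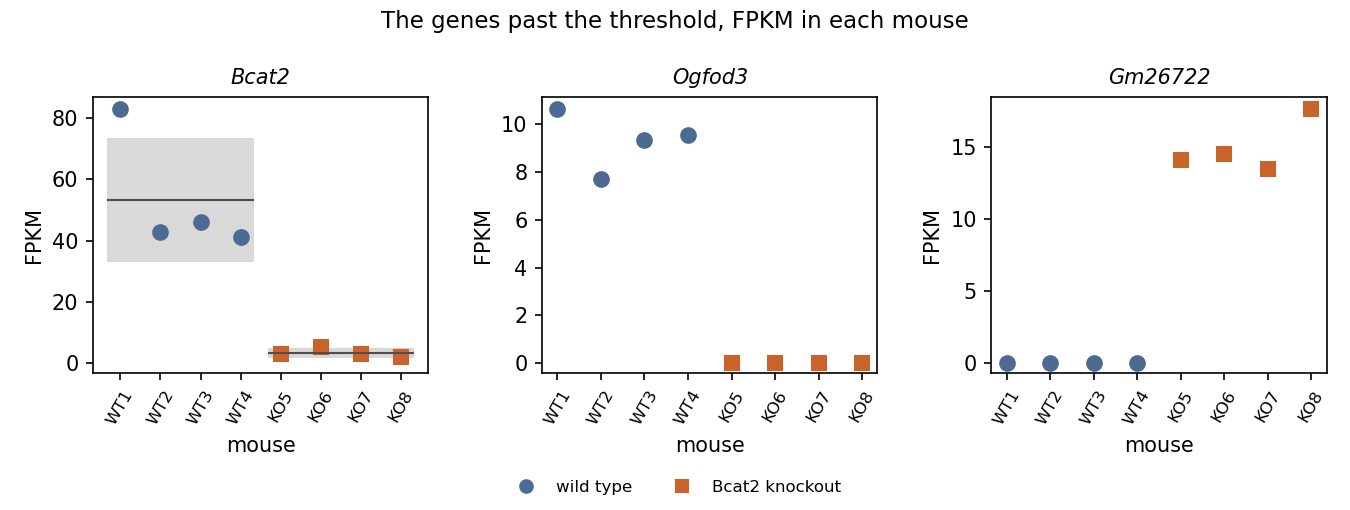
FPKM (vertical axes, from 0) of Bcat2, Ogfod3 and Gm26722 in each of the 8 mice (horizontal axes), with wild type as circles and Bcat2 knockout as squares. In the Bcat2 panel the lines are group means and the grey bands are 1 SD, at 53.2 ± 19.9 and 3.29 ± 1.37 FPKM. Ogfod3 is listed at 0 in every knockout and Gm26722 at 0 in every wild-type mouse.

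Across all genes, which asks what else differs in muscle without BCATm, 3 of the 11118 tested genes passed the threshold, 1 higher and 2 lower in knockouts. Bcat2 was one of them. The second was Ogfod3 (ENSMUSG00000025169, chromosome 11, 121177591 to 121204711), a gene named for an oxygenase domain, at 10.6, 7.73, 9.33 and 9.54 FPKM in wild type and listed at 0 in all 4 knockouts (limma adjusted p = 2.52e-05). The third, chosen after its values were seen, was the non-coding gene model Gm26722 (ENSMUSG00000096944, chromosome 4, 129309081 to 129318443), listed at 0 in all 4 wild-type mice and at 14.1, 14.5, 13.5 and 17.6 FPKM in knockouts (limma adjusted p = 4.89e-06). Both genes overlap another gene on the opposite strand, Hexdc and Rbbp4, so their values are uncertain. Common genes such as Cdk4 and Fdft1 were also listed at 0 in single mice, so a 0 here is a listing and not a measured absence. With 0 as missing only Bcat2 passed (1 gene), but that setting leaves out genes listed at 0 in a whole genotype. It therefore does not test Ogfod3 or Gm26722. The count rose to 9, 8, 6, 8 and 5 genes when WT1, WT2, KO6, KO7 or KO8 was left out, and to 11 without both WT1 and KO6, each time with the same 3 genes among them.

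A further 18 genes were named for the smallest unadjusted p, and none passed (limma adjusted p from 0.057 to 0.48). Among the 12 with lower knockout values, Tmem140 was listed at 2.70, 1.71, 2.95 and 2.70 FPKM in wild type and at 0 in all knockouts (limma adjusted p = 0.057, under the threshold in 14 of its alternatives). Tmem140 overlaps another gene, 3110062M04Rik, so its values are uncertain too. Neat1, the long non-coding RNA that scaffolds paraspeckles, read 252.8 ± 40.0 FPKM in wild type and 125 ± 27.4 FPKM in knockouts (SD, n = 4 each). Cbx3, a heterochromatin protein, read 20.9 ± 1.54 and 9.11 ± 3.32 FPKM, and Zfr, a zinc finger RNA-binding protein, 19.1 ± 1.49 and 10.5 ± 1.23 FPKM. Dnajc7, a co-chaperone, read 87.9 ± 14.9 and 47.6 ± 7.17 FPKM, and the mitochondrial D-lactate dehydrogenase Ldhd 20.9 ± 2.91 and 11.3 ± 2.18 FPKM. Ybx2, Jam2, Tceal5, Abhd11, Mkl1 and Col15a1 had wild-type means of 5.85, 10.3, 15.4, 35.1, 6.86 and 16.9 FPKM against knockout means of 2.81, 5.22, 5.40, 23.7, 3.66 and 7.27 FPKM. Among the 6 with higher knockout values, Inmt, a methyltransferase of indole amines, read 33.9 ± 7.02 and 101 ± 41.1 FPKM, and Ctxn3 52.6 ± 17.4 and 151 ± 60.6 FPKM. Ddit4l, an inhibitor of mTORC1 signalling, read 449 ± 81.5 and 757.5 ± 107 FPKM, and Rps14, a protein of the small ribosomal subunit, 1729 ± 595 and 3582 ± 420 FPKM. Pdlim2 and Gpm6b had means of 6.30 and 2.21 FPKM in wild type and 11.7 and 4.27 FPKM in knockouts. In each of these 18 genes the groups did not overlap, and 751 tested genes (6.75%) did so against 2.86% for a random split. An unadjusted p under 0.05 was reached by 1147 genes, 332 higher and 815 lower in knockouts. Of the 35 splits of the mice into 4 and 4, 4 gave at least as many, the real one included, and the others of these gave 1378, 1661 and 1822. The median of all genes lay at -0.12 on the log2 scale, and median-ratio scaling moved it to -0.002, so list medians are given relative to it. By mouse, the median deviation of all genes from the mean of the 8 mice was -0.351 in KO8. It ran from -0.063 to 0.143 in the other knockouts and from -0.071 to 0.163 in wild type, so KO8 alone lay outside the wild-type range. Gene fold changes and the counts of 332 and 815 genes are not corrected for this offset.

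Of the 30 gene lists, 13 passed the camera threshold, 6 above and 7 below the other genes. That split was 7 and 5 after median-ratio scaling and 5 and 9 after quantile scaling. With an estimated correlation no list passed, at a lowest camera adjusted p = 0.868 with an estimated correlation, and this p holds for each of the 13 lists. The adjustment gave them this shared value. Their unadjusted camera p with an estimated correlation ran from 0.0623 (Schwann cell and nerve markers) to 0.47 (cytosolic aminoacyl-tRNA synthetases).

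Among genes of protein synthesis, 1 list had the smallest camera p of all 30. Cytosolic ribosomal proteins, the structural proteins of the ribosome, lay above other genes in knockouts, with 76 of 77 measured members above the all-gene median and a list median of 0.54 over it on the log2 scale (camera adjusted p = 6.67e-26, but adjusted p = 0.868 with an estimated correlation). Of these, 25 reached an unadjusted p under 0.05, all higher, yet 0 passed over all genes and 0 adjusted over the list alone by limma. Relative list medians ran from -0.64 to -0.07 in the wild-type mice and from -0.03 to 0.59 in the knockouts. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, had a list median of -0.10 relative to all genes over 20 members (camera adjusted p = 0.0218, and adjusted p = 0.868 with an estimated correlation), with Farsa at 9.73 ± 0.858 and 7.34 ± 0.95 FPKM. Their call ended when WT2, WT3, KO7 or KO8 was left out (camera adjusted p = 0.0577, 0.108, 0.0562 and 0.116), and with array weights (0.128). Translation initiation and elongation factors (camera adjusted p = 0.21, but 0.0334 with median-ratio scaling) and mTORC1 and nutrient-sensing genes (camera adjusted p = 0.477) did not pass. Of the former, Eef1a2, the muscle form of elongation factor 1A, had means of 477.5 and 328 FPKM, and of the latter Ddit4l is given above.

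In protein breakdown, proteasome subunits passed, with 27 of 40 above the all-gene median and a list median 0.14 over it (camera adjusted p = 0.0305, and adjusted p = 0.868 with an estimated correlation). Psmb3 read 161 ± 38.5 and 231 ± 11.4 FPKM (SD, n = 4 each), and 0 members passed over all genes or adjusted over the list alone by limma. This call ended when WT3, WT4 or KO5 was left out (camera adjusted p = 0.108, 0.0886 and 0.157). It also ended with no filter (0.123), a filter at a mean of 5 FPKM (0.105), quantile scaling (0.378) and the length and GC trend removed (0.114 by camera, with a median still 0.14 over all genes). Muscle ubiquitin ligases and atrophy genes did not pass (camera adjusted p = 0.848), nor did autophagy and lysosome genes (camera adjusted p = 0.477). Eda2r, a receptor of the TNF receptor family, read 4.45 ± 1.45 and 9.98 ± 5.23 FPKM, and Map1lc3a, an autophagosome protein, 237.8 ± 39.7 and 304 ± 37.8 FPKM. The ubiquitin ligases Trim63 and Fbxo32, chosen after their values were seen, were highest in KO5, at 426 and 179 FPKM, against 111 to 225 FPKM and 22.7 to 88.0 FPKM in the other 7 mice.

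Genes of branched-chain amino acid breakdown had a list median of -0.12 relative to all genes, with 18 of 24 measured members under the all-gene median (camera adjusted p = 0.0125, and adjusted p = 0.868 with an estimated correlation). Relative list medians ran from -0.06 to 0.33 in wild type, highest in WT1, and from -0.12 to 0.05 in knockouts, so the groups overlapped. Bcat2 itself was the only member past the threshold, over all genes and adjusted over the list alone. Without Bcat2 the other 23 members no longer passed (camera adjusted p = 0.0521), though their median stayed at -0.11, with 17 of 23 under the all-gene median, and the call also ended without WT1 or KO7 (camera adjusted p = 0.11 and 0.0702). Chosen after their values were seen, Ivd, which acts on isovaleryl-CoA from leucine, read 49.6 and 29.1 FPKM, and Bckdk and Bckdha, the kinase and a subunit of the branched-chain keto acid dehydrogenase, 118 and 79.7 FPKM and 79.97 and 60.9 FPKM. Genes of glutamate, glutamine, alanine and aspartate metabolism (camera adjusted p = 0.102, but 0.0272 with no filter), amino acid transporters (0.448), ATF4 and integrated stress response targets (0.164) and polyamine metabolism (0.841) did not pass camera. Their members with the smallest p were Ampd1, an AMP deaminase, at 809.6 and 620.0 FPKM, Slc7a8 at 2.44 and 1.26 FPKM, Ddit4 at 3.79 and 11.3 FPKM and Amd1 at 122 and 67.1 FPKM.

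Lists of energy metabolism went in different directions. TCA cycle genes lay below other genes, with 19 of 26 under the all-gene median and a list median of -0.18 (camera adjusted p = 0.000797, and adjusted p = 0.868 with an estimated correlation), and 10 of them had an unadjusted p under 0.05, all lower. Dlat, a subunit of pyruvate dehydrogenase, read 95.03 ± 15.7 and 56.0 ± 11.5 FPKM, and citrate synthase (Cs), chosen after its values were seen, 215.5 and 129.8 FPKM. Glycolysis and glycogen genes had a list median of -0.16 (camera adjusted p = 0.0145) and genes of fatty acid uptake and oxidation one of -0.19 (camera adjusted p = 0.0154), each with adjusted p = 0.868 with an estimated correlation. Pgam2, the muscle phosphoglycerate mutase, read 1872 ± 251 and 1404 ± 80.6 FPKM, and Etfdh, which passes electrons from fatty acid oxidation to ubiquinone, 58.2 ± 8.18 and 41.2 ± 2.57 FPKM. Both calls ended with median-ratio scaling (camera adjusted p = 0.153 and 0.0602). The glycolysis call also ended without WT2, KO6 or KO7 (0.0781, 0.0832 and 0.0806 by camera), and the fatty acid call without WT1, WT4, KO5 or KO7 (0.11, 0.0998, 0.0629 and 0.0562 by camera) or both WT1 and KO6 (0.124). Oxidative phosphorylation subunits lay above other genes, with a list median 0.17 over all genes (camera adjusted p = 0.0138, and adjusted p = 0.868 with an estimated correlation), but lay below them after quantile scaling (camera adjusted p = 0.0271). Their members went both ways, with 11 higher and 8 lower at an unadjusted p under 0.05, and Ndufs1 of complex I at 153.8 ± 17.5 and 109.7 ± 8.96 FPKM. Without WT3, KO5 or KO8 that call ended (camera adjusted p = 0.333, 0.0898 and 0.434), as it did with no filter (0.196), a filter at a mean of 5 FPKM (0.0565), array weights (0.768) and the length and GC trend removed (0.124, with a median of 0.13). In these 4 lists 0 members passed over all genes or adjusted over the list alone by limma.

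Slow fibre contractile genes had a list median 0.58 above all genes, with 12 of 12 members over it (camera adjusted p = 0.00741, and adjusted p = 0.868 with an estimated correlation), yet 0 members reached an unadjusted p under 0.05. The smallest p was that of Casq2, the slow and cardiac calsequestrin, at 13.45 ± 2.34 and 18.4 ± 5.73 FPKM. The call ended without WT2 or KO5 (camera adjusted p = 0.315 and 0.0898), the mice with the lowest and the highest relative list medians of -1.49 and 1.24. Fast fibre genes did not pass (camera adjusted p = 0.479, but 0.0208 with quantile scaling), with the fast calsequestrin Casq1 at 1227 ± 255 and 829.9 ± 108 FPKM. Myh4, the fastest myosin heavy chain, chosen after its values were seen, read 2814, 4491, 4798 and 4071 FPKM in wild type and 2684, 2154, 3121 and 2506 FPKM in knockouts (limma adjusted p = 0.48).

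Glucocorticoid receptor targets lay 0.43 above all genes, with 18 of 21 members over the median (camera adjusted p = 0.00299, and adjusted p = 0.868 with an estimated correlation). Cebpd, a transcription factor induced by glucocorticoids and inflammation, read 46.1 and 32.7 FPKM in KO5 and KO6, 9.16 and 10.6 FPKM in KO7 and KO8, and 5.69 ± 0.374 FPKM in wild type (SD, n = 4). Relative list medians were 0.48 in KO5 and 0.53 in KO6, but -0.04 in KO7 and -0.25 in KO8, against -0.31 to -0.05 in the wild-type mice. Without WT1 and KO6, the mice with raised fat transcripts, the list no longer passed and its median was 0.22 (camera adjusted p = 0.157). Denervation and regeneration genes (camera adjusted p = 0.258), clock genes (0.549) and immediate early and heat shock genes (0.0826) did not pass camera. The last list passed with no filter (0.0272), quantile scaling (0.0427), array weights (0.0111), ranks (0.047), the length and GC trend removed (0.026), or WT3 or KO8 left out (camera adjusted p = 0.0312 and 0.00358). Its relative medians were 0.36 in KO5 and 0.80 in KO6, against -0.31 to 0.01 in the other 6 mice. Sln, the sarcolipin that inhibits the calcium pump, read 287, 48.5, 18.0 and 9.88 FPKM in the knockouts and 4.21 ± 2.54 FPKM in wild type (limma adjusted p = 0.48). The clock repressor Bhlhe41 had means of 10.1 and 5.99 FPKM, and Cyr61, a matricellular protein, 7.43 and 14.2 FPKM.

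Among markers of other cells of muscle, Schwann cell and nerve genes lay 0.70 above all genes in knockouts, with 11 of 11 members over the median (camera adjusted p = 1.21e-06, and adjusted p = 0.868 with an estimated correlation). Ncmap, a myelin-associated protein, read 0.917 ± 0.234 and 2.87 ± 1.77 FPKM, and the myelin gene Mbp, chosen after its values were seen, 14.2 and 25.7 FPKM. Fibroblast and matrix genes lay below all genes, with 19 of 24 under the median and a list median of -0.43 (camera adjusted p = 0.000797, and adjusted p = 0.868 with an estimated correlation). Col15a1, Col6a1, Col6a2 and Col5a1 passed when adjusted over the list alone by limma, and none of them over all genes. Col15a1 read 16.9 ± 5.85 and 7.27 ± 0.965 FPKM, and Col6a1, named after its values were seen, 19.3 and 8.96 FPKM. Endothelial markers had a list median of -0.27 (camera adjusted p = 0.0125, and adjusted p = 0.868 with an estimated correlation), with the endothelial cadherin Cdh5 at 18.0 ± 3.93 and 11.3 ± 2.11 FPKM. Both calls ended without WT1 and KO6 together (camera adjusted p = 0.132 and 0.182), where the fibroblast median went from -0.43 to -0.15 and the endothelial one from -0.27 to -0.26. The endothelial call also ended without KO6 (camera adjusted p = 0.063), with a filter at a mean of 5 FPKM (0.0908) and with array weights (0.0512). Smooth muscle and pericyte (camera adjusted p = 0.102), macrophage and leukocyte (0.102, but 0.0117 without WT1, 0.0138 without KO5 and 0.047 on ranks), tendon (0.386, but 0.0498 without WT1 and 0.029 without KO7), erythroid (0.477) and adipocyte markers (0.45) did not pass camera. Their members with the smallest p were Pdgfrb at 6.39 and 3.93 FPKM, Lyz2 at 101 and 158 FPKM, Kera at 13.4 and 7.92 FPKM, Hba-a1 at 120 and 77.4 FPKM and Plin4 at 26.4 and 17.95 FPKM. Without WT1 and KO6 the adipocyte markers lay 0.58 above all genes in the remaining knockouts (camera adjusted p = 0.000634, and adjusted p = 0.973 with an estimated correlation).

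**Figure D3:**
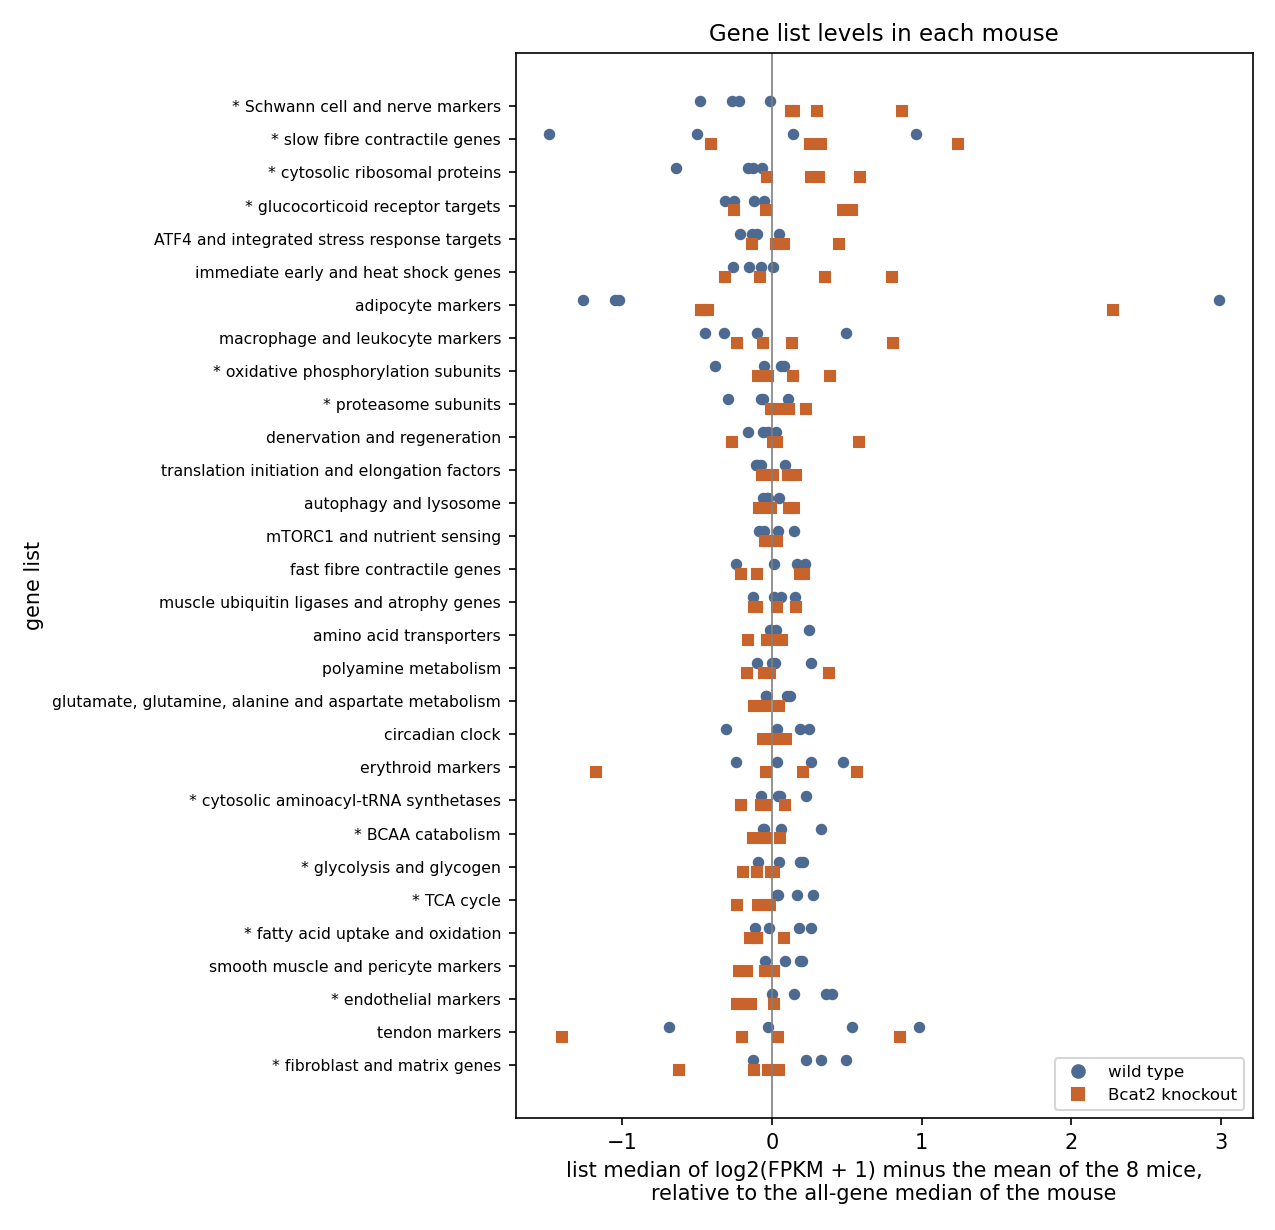
Median level of each of the 30 gene lists in each mouse (horizontal axis, log2(FPKM + 1) as deviation from the mean of the 8 mice and relative to the all-gene median of the mouse), with wild type as circles and Bcat2 knockout as squares. Lists are ordered by their genotype difference, and a star marks the 13 with a camera adjusted p under 0.05, none of which held with an estimated correlation (adjusted p = 0.868). Ribosomal medians run from -0.64 to -0.07 in wild type and from -0.03 to 0.59 in knockouts.

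Among the 11118 tested genes, the authors' deposited table flags 2250 at p < 0.05, against 1147 with an unadjusted limma p under 0.05. The 3 genes called above passed an adjusted p, so that count is not comparable with the flags. Over all rows of the authors' deposited table, tested or not, 2484 carry the flag for p < 0.05 and 1214 the flag for p < 0.001. Of the 2484, 1003 had the higher mean in knockouts and 1481 the lower. The flagged share at the first threshold rose with expression, from 7.93% of rows at a mean of 1 to 3 FPKM to 89.5% at 1000 FPKM or more. Ckm, the muscle creatine kinase, is flagged at p < 0.001 in the authors' deposited table with means of 11814.5 and 11711.6 FPKM. So small a difference was rare among flagged genes. Of the 1203 tested genes with the stricter flag, 17 had a log2 change under 0.1 in size. Of the 2250 tested genes with the first flag, 666 had an unadjusted limma p under 0.05, and 389 had groups that did not overlap.

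**Figure D4:**
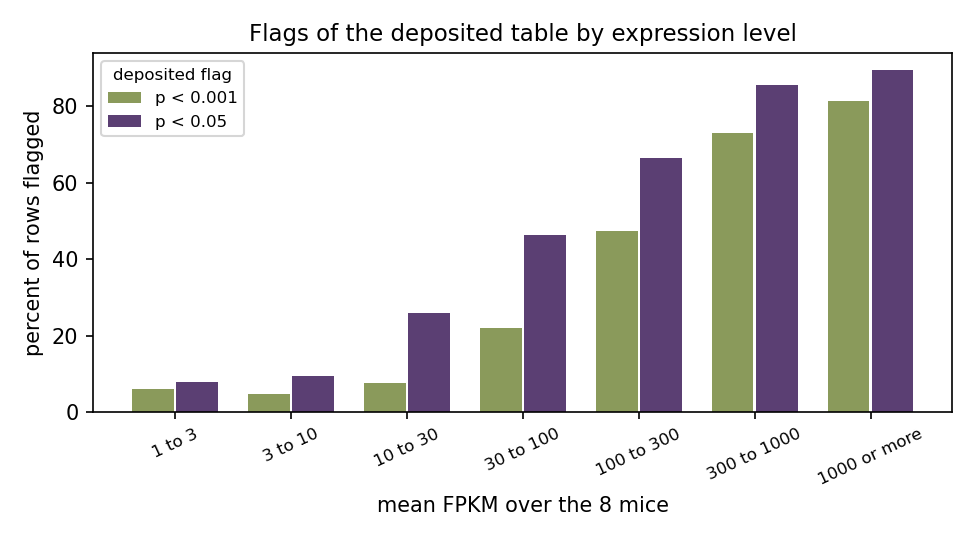
Percent of rows carrying each flag of the authors' deposited table (vertical axis, from 0) by mean FPKM over the 8 mice (horizontal axis), with 1 bar for each of the 2 flags. The share with the less strict flag goes from 7.93% in the lowest class to 89.5% in the highest.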

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

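In this part, the tests of the fat, skin and zero patterns, of library depth and of the smallest camera p over the splits, and the length and GC correction, were chosen only after the results were seen. A mouse is listed here when its gap to the nearest of the other 3 mice of its genotype exceeded 0.829 of the group's whole range, which chance does in about 1 in 20 groups. It happened in 13 of 184 groups.

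Bcat2 in WT1 read 83.0 FPKM, against 41.2 to 46.0 FPKM in the other wild-type mice. Among the knockouts it was highest in KO6, at 5.26 FPKM. WT1 and KO6 are the libraries with raised fat transcripts, and a link to Bcat2 was not tested. In WT3, Casq1 read 1609 FPKM against 1091 to 1116 FPKM, and Slc7a8 read 3.71 FPKM against 1.97 to 2.09 FPKM. In KO8, Cs read 91.98 FPKM against 138.5 to 144.7 FPKM, and Pdgfrb read 2.72 FPKM against 4.29 to 4.37 FPKM. Amino acid transporters had a relative list median of 0.25 in WT3, against -0.01 to 0.03 in the other wild-type mice. Krt14 read 0.0808 FPKM in WT2 and was listed at 0 in the other wild-type mice.

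Ribosomal protein genes were lowest in WT3, with a relative list median of -0.64 against -0.16 to -0.07 in the other wild-type mice, and they had the smallest camera p of the lists. Of the 35 splits of the mice, 1 gave a list median as far from that of all genes, the real one at 0.54 against 0.53 with WT2 and KO7 exchanged, but the list was singled out of 30, and 2 of the 35 gave a smallest camera p over all lists as small (-log10 p of 26.65 in the real one and 26.66 in that other), so chance cannot be excluded. Removing a trend on transcript length and GC percent left a median of 0.48, and adding depth as a covariate left 0.50 (camera adjusted p = 1.02e-24), so neither is the whole source. A shift of reads from pseudogenes to the ribosomal protein genes would lower the pseudogenes. Instead all 11 tested ribosomal pseudogenes lay above the all-gene median, at a median of 0.53 over it (exact sign test p = 0.000977). That sign test counts the pseudogenes as independent, although they were measured in the same mice, so its p may be too small. Reads of the ribosomal protein genes assigned to similar pseudogenes would also raise the pseudogenes, so the test cannot decide whether reads were traded. A genotype effect may remain, as a hypothesis, beside age and body weight, which were not tested because knockout columns are not tied to labelled mice. Handling of the single samples, which no label records, and the free choice between the diets were not tested either. No list call held with an estimated correlation (camera adjusted p = 0.868).

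Sync, the gene next to Gm26722, was listed at 0 in WT1, against 6.58 to 9.86 FPKM in the other wild-type mice, and at 5.39 FPKM in KO7, against 0 in the other knockouts. Of 97 tested genes listed at 0 in exactly 4 mice, 4 split by genotype (Gm26722, Ogfod3, Tmem140 and the skin gene Lce1m), against 2.77 for zeros that fall on any 4 mice (1-sided exact binomial p = 0.301). Failed estimates that happen to fall on one genotype stay a candidate source. The test pools all genes with 4 zeros and so decides nothing for a single gene such as Ogfod3 or Gm26722. Foreign DNA carried along with the targeted Bcat2 locus would place such genes on chromosome 7, and 0 of the 4 lie there. Of 147 genes with a median FPKM above 5 that were listed at 0 in some mouse, 76.9% overlap another gene, against 42.5% of the other tested genes (Fisher exact p = 4.97e-17). The other tested genes were not limited to a median above 5 FPKM, so the sets may also differ in level. Hexdc, which overlaps Ogfod3, read 34.4 ± 2.11 FPKM in wild type and 49.1 ± 4.40 FPKM in knockouts (SD, n = 4 each).

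Fat and skin transcripts set 2 libraries apart. The relative list median of adipocyte markers was 2.98 in WT1, against -1.26 to -1.02 in the other wild-type mice, and 2.28 in KO6, against -0.47 to -0.42 in the other knockouts. WT1 and KO6 held both top values for 92.3% of the 13 adipocyte markers, with Fabp4, the most abundant, at 9310 and 5710 FPKM against 495 to 1510 FPKM elsewhere, so adipose tissue in these samples may be the source. Whether genotype adds to these levels stays open, because 1 very high mouse in each genotype widens the spread of the comparison (camera adjusted p = 0.45), and without WT1 and KO6 the list lay 0.58 above all genes in knockouts (camera adjusted p = 0.000634, but 0.973 with an estimated correlation). Krt14 at 108 FPKM in KO6, against 0 to 0.365 FPKM in the other knockouts, went with 95% of the 20 keratinocyte markers at least 2-fold above every other mouse, with Krtdap at 910 FPKM, and skin in that sample is a candidate source.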

How the results depend on the processing

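The alternatives that left out WT1 and KO6, corrected length and GC, treated zeros or the Myh4 value of WT2 as missing, took Bcat2 from its list or used depth as a covariate were chosen after seeing the data. No paired analysis was possible because the knockout columns carry no replicate number of the labels. For the same reason the alternatives with age or body weight as a covariate and with 10-week-old mice only were not run. Bcat2 kept its direction and passed limma under every gene-level alternative run, from -3.85 to -3.42 on the log2 scale with 1 mouse left out, at limma adjusted p from 0.000381 to 0.0415 over all of them. The count of genes changed went from 3 to between 4 and 9 with 1 mouse left out, to 11 without WT1 and KO6, and to 1 with zeros as missing, which removes the genes listed at 0 in a whole genotype. The cause of the higher counts was not tested. The count of gene lists went from 13 to 0 with an estimated correlation, which widens the error by the correlation seen among few mice, and stayed between 10 and 15 otherwise. Named genes gave 1445 of 1459 alternative values on the same side of the threshold, and the other 14 were Tmem140 passing it. Only 3 of the 64 named genes passed in the main fit. Most of the 1445 are therefore genes that passed in neither fit, which says little about their changes. By camera, oxidative phosphorylation subunits reversed under quantile scaling (adjusted p = 0.0271), and the cause was not tested. Lists that did not pass also changed direction without passing. Muscle ubiquitin ligases did so with median-ratio scaling (0.975), array weights (0.826) and the length and GC correction (0.859), polyamine genes with median-ratio scaling (0.92) and erythroid markers without WT1 and KO6 (0.407). With 1 mouse left out, camera adjusted p ran from 0.315 to 0.992 for ubiquitin ligases, 0.318 to 0.93 for polyamine genes, 0.103 to 0.791 for fast fibre genes, 0.111 to 0.941 for clock genes and 0.0702 to 0.912 for erythroid markers. It ran from 0.000984 (WT1 left out) to 0.992 for adipocyte and from 0.029 (KO7 left out) to 0.992 for tendon markers. Read totals are not known, so no limit from depth can be given.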

Other observations

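Of the splits of the mice, 12 of 35 gave at least the 3 genes of the real one, and the highest other count was 12, for WT1, KO5, KO6 and KO8 against the rest. Chance cannot be excluded for the count, and a split with several times the real count may point to a structure of the samples, but whether the highest of the other counts exceeds what chance gives was not tested. At an unadjusted p under 0.05, a count of splits made after the result was seen, 4 of the 35 gave at least the 1147 genes of the real one, with 1822 as the highest other, so chance cannot be excluded for that count. For gene lists, 7 of the 35 splits gave at least 13, with 19 as the highest other count, so chance cannot be excluded there either.

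Genes within 10 Mb of Bcat2, where foreign DNA linked to the targeted locus may lie, had an unadjusted limma p under 0.05 in 16 of 103 cases (15.5%), against 10.3% elsewhere (odds ratio 1.61, 95% interval 0.878 to 2.77, Fisher exact p = 0.1), which leaves this hypothesis open because the interval spans 1.

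KO5 held the highest values among the 8 mice of several genes, a pattern noticed after the values were seen. Sln read 287 FPKM there, Trim63 426 FPKM, Fbxo32 179 FPKM and Cebpd 46.1 FPKM, and its relative list median was 0.58 for denervation and regeneration genes, against -0.27 to 0.04 in the other mice. Thrsp, a lipogenic gene, read 217 FPKM in KO6, 59.9, 53.2 and 23.4 FPKM in the other knockouts, and 13.9 to 18.9 FPKM in the 3 wild-type mice with a value. KO6 is one of the 2 libraries with raised fat transcripts and the other, WT1, is the mouse with no Thrsp value.

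Transcript length and GC percent went with the genotype difference across genes (Spearman's rho of -0.15 and -0.17 over 11024 genes, which are not independent replicates). The median log2 change was 0.07 in the shortest 10% of transcripts and -0.20 in the longest 10%.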
